A study of Mus musculus with 28 samples.

How the data were processed

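Per the labels, cells were seeded on collagen and grown in Iscove's medium with fetal bovine serum, pellets were frozen after trypsin, RNA was taken with TRIzol, and libraries were prepared from 500 ng of RNA with a stranded mRNA kit. Day 0 libraries had received neither ethanol nor hormone. Groups and replicate numbers from the labels matched all 28 columns.

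The deposited values are log2 CPM (counts scaled to the library total), normalized by the authors per the file name. Per the submitters' processing notes, kallisto (no version given), edgeR 3.40.1 and limma 3.54.0 were used with the build mm10, with no role or order stated, and the annotation, the prior count and the normalization method were not given in the sources used here. Taken back from the log, the values of a library sum to between 949631 and 1059930 CPM, and the lowest value, -4.15, is shared by all libraries, in which 6 to 42 values stand at it. Counts were not used here. Low values shared by at least 3 genes fell on steps in each library (100%), but only 12.9 to 20.6% of all its low values did (tolerance 0.02), so no count model was fitted. The smallest root mean square log2 difference between any 2 libraries was 0.282, so no library was a copy of another. An entry without a gene symbol, which took 0.0267 to 0.0698% of CPM, was left out of the tests.

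Genes with log2 CPM above 0 in at least 4 libraries were kept, which removed none, and 13128 genes were tested. A linear model with 1 mean per group was fitted to all 28 libraries with limma 3.58.1 in R 4.3.3 (21 residual degrees of freedom), followed by empirical Bayes moderation with an intensity trend. The contrasts were corticosterone against vehicle at days 3, 6 and 9, vehicle at days 3, 6 and 9 against day 0, and the corticosterone effect at day 6 and at day 9 against that at day 3. Benjamini-Hochberg adjusted p under 0.05 called a gene, within each contrast, and the text writes rose or fell of such genes and lists. Values are log2 fold changes ± SE of the contrast with n = 4 libraries per group unless stated otherwise. Data were simulated for corticosterone against vehicle at day 3. Of 50 genes each, 44, 78, 94 and 100% were recovered at planted log2 changes of 0.25, 0.5, 1 and 2, with 9 false calls among 12898 unchanged genes. Real spread was largest in treated day 3 libraries.

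Before the data were examined, the groups, contrasts, tests, filter, thresholds, alternatives, 39 gene lists and the rule for named genes were fixed. The rule took, for the 3 corticosterone contrasts and vehicle day 9 against day 0, the 10 largest rises and 10 largest falls with adjusted p under 0.05, a mean log2 CPM of at least 1 over the 8 libraries and all 4 libraries of one group above all 4 of the other, and, for the remaining contrasts, the 5 largest in each direction with adjusted p under 0.05 and the same minimum. The receptor genes and canonical targets were named whatever their values, and predicted gene models were to be passed over, which removed 0. From each described list the 2 members with the smallest p were named, where the rule allowed up to 4, and 4 members that would have been among them are not reported here. That number and the choice of which called lists to describe with examples were made after the values were seen. Folds against groups near the lowest value depend on the prior count the authors added.

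The lists, of pathways and of markers for cells the culture could hold, are those named beside the results. The 35 lists with at least 5 measured members were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, adjusted over the lists of a contrast. Beside it stand camera with an estimated correlation and fry, whose p asks whether a list's genes move one way on balance and compares them with no other genes. For each list, members were also adjusted over the list alone.

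The share of CPM on mitochondrially encoded genes was compared by exact permutation of the 8 libraries of a day. Transcript lengths came from the GENCODE M21 annotation of GRCm38, joined by symbol, for 12918 genes (98.4%). Alternatives, 1 choice at a time, were a stricter filter (log2 CPM above 2 in at least 4 libraries, 11460 genes), no filter, median centring, quantile normalization, log2(CPM + 1) and log2(CPM + 5), only the groups compared, no intensity trend, robust moderation, weights per library, replicate number as a fixed or random block (statmod 1.5.0), adjusted p under 0.01, at least 2-fold change, and leaving out each library in turn. Removing a trend with transcript length (lowess, span 0.3) and recounting lists without single libraries that stood apart were added after seeing the data. The libraries of each contrast were split in all 35 ways into groups of 4 or, for contrasts between days and for shared calls, 100 times at random. The splits of contrasts between days used values with the additive effects of day and treatment removed. Intervals of medians were bootstrapped over genes (10000 draws). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.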

Results

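To follow how epididymal epithelium responds to a glucocorticoid and recovers from it, strand-specific mRNA libraries were sequenced from DC2 cells, an immortalized line from the distal caput of the mouse epididymis, where sperm mature. Confluent cultures received corticosterone, the main glucocorticoid of rodents, at 500 ng/ml in ethanol, or the ethanol vehicle at 0.1%, and the medium was replaced on day 3 and on day 6. Vehicle libraries came from day 0, before treatment, and from days 3, 6 and 9, and corticosterone libraries from days 3, 6 and 9, 4 libraries each and 28 in all. Day 3 was the end of the treatment, and days 6 and 9 lay 3 and 6 days after it. The deposited table held normalized log2 CPM (counts scaled to the library total) for 13129 entries, of which the 13128 with a gene symbol were tested. Counts per library were not used here.

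To determine whether treated cultures carried a glucocorticoid response and how long it lasted, the receptor gene and textbook targets were examined first. Fkbp5, a cochaperone of the receptor, was higher with corticosterone by 3.05 ± 0.12 (log2 fold change ± SE, n = 4 per group) at day 3, by 2.61 ± 0.12 at day 6 and by 0.74 ± 0.12 at day 9. Tsc22d3, the leucine zipper gene known as GILZ, rose by 2.69 ± 0.14 and 2.45 ± 0.14 at days 3 and 6 and was at 0.36 ± 0.14 (adjusted p = 0.05995) at day 9, called with quantile normalization, library weights or the groups alone (0.34 to 0.37). Sgk1, the serum- and glucocorticoid-regulated kinase, stood at 9.38 ± 0.13 log2 CPM (mean ± SD) against 3.25 ± 0.15 in vehicle at day 3, a rise of 6.13 ± 0.28. Its rise at day 6 was 4.94 ± 0.28. At day 9 it was lower, at -0.77 ± 0.28 (adjusted p = 0.0435), a call that ended with log2(CPM + 1), with log2(CPM + 5), without the intensity trend, and without any 1 of 7 of the 8 libraries (-0.82 to -0.65). The clock gene Per1 rose by 2.02 ± 0.08 and 1.66 ± 0.08 and then fell below vehicle, to -0.34 ± 0.08 at day 9. Klf9, a Kruppel-like repressor, rose by 1.60 ± 0.10 and 1.60 ± 0.10 and was at -0.19 ± 0.10 (adjusted p = 0.159) at day 9, called with library weights (-0.20) or the groups alone (-0.19).

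Nr3c1 itself, the glucocorticoid receptor gene, fell by 1.26 ± 0.10 at day 3 (adjusted p = 8.3e-11) and by 0.98 ± 0.10 at day 6 (adjusted p = 6.8e-09). At day 9 its value was -0.31 ± 0.10 (adjusted p = 0.0210), a call that ended without vehicle replicate 6 (-0.28), corticosterone replicate 3 (-0.27) or corticosterone replicate 4 (-0.29). The mineralocorticoid receptor gene Nr3c2 was not called on any day (-0.08, 0.01 and 0.06 at days 3, 6 and 9). Hsd11b2, whose enzyme inactivates corticosterone, was lower at day 3 (-0.45 ± 0.16 (adjusted p = 0.0222)) and higher at day 6 (0.45 ± 0.16 (adjusted p = 0.0230)) and day 9 (1.47 ± 0.16 (adjusted p = 1.2e-07)). Its day 3 call ended without vehicle replicate 4 (-0.43) or 6 (-0.40), and its day 6 call without vehicle replicate 3 (0.40), without corticosterone replicate 6 (0.24) or with the compared groups fitted alone. Dusp1, a phosphatase of MAP kinases, was at -0.08 ± 0.07 (adjusted p = 0.388) at day 3, fell to -0.19 ± 0.07 (adjusted p = 0.0304) at day 6 and to -0.44 ± 0.07 (adjusted p = 3.6e-05) at day 9. Its day 6 call was lost with quantile normalization, with the replicate block and without any 1 of 4 libraries (-0.18 to -0.15). The metallothionein gene Mt2 rose by 0.92 ± 0.11 at day 3, was at 0.22 ± 0.11 (adjusted p = 0.107) at day 6 (called with library weights, 0.31, or without vehicle replicate 5, 0.29, or corticosterone replicate 6, 0.32) and was lower at day 9, at -0.65 ± 0.11 (adjusted p = 7.7e-05).

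**Figure D1:**
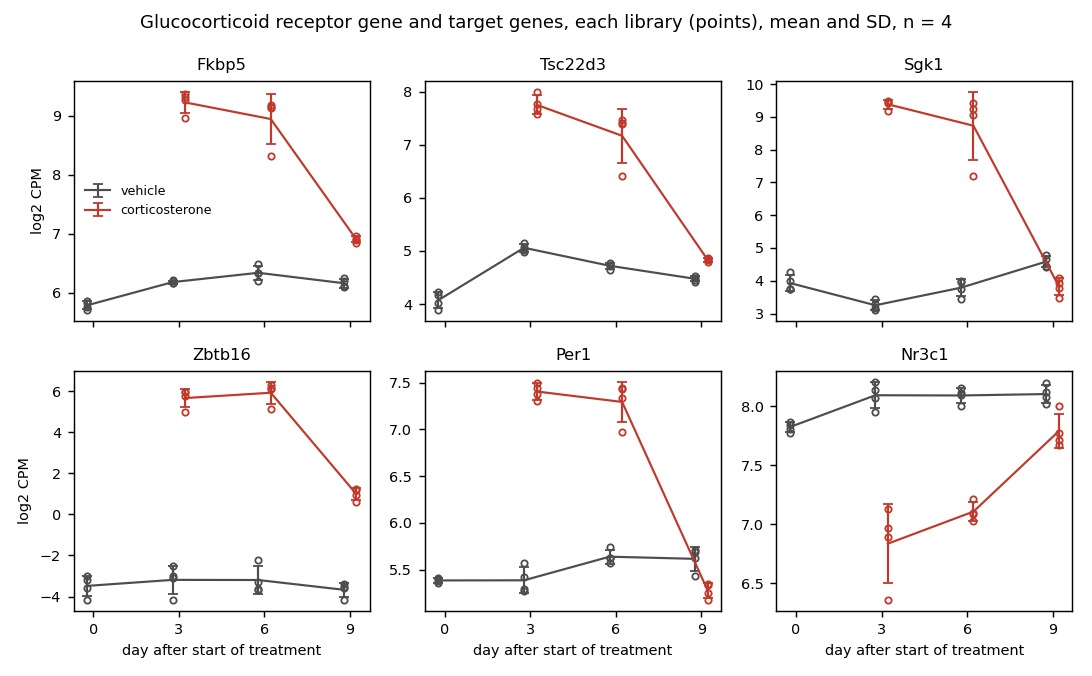
Log2 CPM of 5 target genes and of Nr3c1 by day, with each library as a point and lines through the means ± SD (n = 4 per group), vehicle in grey and corticosterone in red. The 5 targets lay above vehicle at days 3 and 6, and Nr3c1 lay below it.

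To determine what 3 days of corticosterone changed, treated and vehicle libraries of day 3 were compared. Among genes within the limits set for all rankings here (a mean of at least 1 log2 CPM over the libraries compared and, for each single day of corticosterone and vehicle day 9, no overlap between groups), the largest rises were in Folh1, a membrane carboxypeptidase gene, at 9.47 ± 0.47 (adjusted p = 8.3e-15), and in Zbtb16, a zinc finger transcription factor, at 8.85 ± 0.35 (adjusted p = 1.3e-16). Folh1 reached 5.98 ± 0.08 log2 CPM from -3.49 ± 0.91 and Zbtb16 5.66 ± 0.46 from -3.19 ± 0.69, and because 2 and 1 vehicle libraries stood at the lowest value of the table, these folds depended on the prior count (5.86 and 5.53 with log2(CPM + 1)). Among the other large rises were the aldehyde dehydrogenase gene Aldh1a7 at 6.94 ± 0.29, Sgk1, the KANK family adaptor gene Kank4 at 5.51 ± 0.36, Spink8 at 5.05 ± 0.30 and Trim67, of the tripartite motif family, at 4.95 ± 0.10. Ifi207, of an interferon-inducible family, followed at 4.85 ± 0.15, the insulin-like growth factor binding protein gene Igfbp4 at 4.43 ± 0.35 and Lcn2, a siderophore-binding lipocalin, at 4.39 ± 0.23.

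The largest falls within these limits were in Spp1, which encodes the secreted glycoprotein osteopontin, at -3.75 ± 0.32 (adjusted p = 2.0e-10), and in the leukocyte adhesion molecule gene Vcam1, at -3.09 ± 0.15 (adjusted p = 5.4e-15). Others were the cadherin gene Cdh6 at -2.75 ± 0.09, the epithelial integrin gene Itgb6 at -2.69 ± 0.07, the sialic acid-binding lectin gene Siglecg at -2.82 ± 0.27 and the TNF receptor family gene Tnfrsf9 at -2.46 ± 0.18. Rsad2, which encodes the antiviral protein viperin, was at -2.73 ± 0.18, Hpgds, a prostaglandin D synthase gene, at -2.55 ± 0.30, Samd5 at -2.82 ± 0.18 and Nrep at -2.66 ± 0.14. In limma 3065 genes were higher and 3364 lower at adjusted p under 0.05 (49.0% of those tested), of which 478 and 428 changed at least 2-fold. The p-values measure only the pooled spread within all 7 groups, as the labels do not say whether replicates were separate cultures. Reads of close paralogs such as Aldh1a7 and Aldh1a1 may not be fully separated.

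Genes of mitochondrial energy metabolism rose together at day 3. Of the 65 nuclear-encoded subunits and assembly factors of oxidative phosphorylation, 65 rose (65 higher adjusted over the list alone). Their median was 0.63 (camera adjusted p = 6.6e-22, adjusted p = 0.191 with an estimated correlation). Cycs, which encodes cytochrome c, was higher by 0.88 ± 0.07 and Cyc1, of the cytochrome bc1 complex, by 0.84 ± 0.07. Corticosterone replicate 4 stood apart on this list, with a mean of 7.70 log2 CPM against 7.10 to 7.17 in the other 3 treated libraries, and without it 65 members were still higher, with a median of 0.48. Of the 22 genes of the tricarboxylic acid cycle, which feeds electrons to the respiratory chain, 22 rose (22 higher adjusted over the list alone). Their median was 0.51 (camera adjusted p = 6.7e-12, adjusted p = 0.00997 with an estimated correlation). Pdha1, a pyruvate dehydrogenase subunit, rose by 0.74 ± 0.04 and Idh3a, of isocitrate dehydrogenase, by 0.57 ± 0.04, and replicate 4 again had the highest list mean (7.60 against 7.41 to 7.44). Of the 23 genes of mitochondrial fatty acid oxidation, 18 rose and 5 were not called (18 higher and 1 lower adjusted over the list alone). Their median was 0.40 (camera adjusted p = 4.5e-07, adjusted p = 0.0845 with an estimated correlation). Pdk4, a kinase that restrains pyruvate oxidation, was higher by 2.59 ± 0.17 and the electron transfer gene Etfdh by 0.51 ± 0.04. Of the 11 transcripts of the mitochondrial genome, 10 rose and 1 was not called (10 higher adjusted over the list alone). Their median was 0.43 (camera adjusted p = 0.000219, adjusted p = 0.218 with an estimated correlation), and a median of 0 that was not called under quantile normalization (camera adjusted p = 0.792). The cytochrome oxidase genes mt-Co1 and mt-Co2 were higher by 0.56 ± 0.05 and 0.65 ± 0.08, calls that ended under quantile normalization (0 and 0.07), which ties the most abundant transcripts.

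Receptor targets, clock genes and metal-binding genes rose as well. Of the 29 genes set down as glucocorticoid receptor targets, 24 rose, 2 fell and 3 were not called (24 higher and 2 lower adjusted over the list alone). Their median was 1.60 (camera adjusted p = 5.7e-16, adjusted p = 0.0313 with an estimated correlation). Of the 18 genes of the circadian clock, 10 rose, 4 fell and 4 were not called (10 higher and 4 lower adjusted over the list alone). Their median was 0.34 (camera adjusted p = 0.00206, adjusted p = 0.124 with an estimated correlation). The period gene Per2 rose by 1.70 ± 0.08. Of the 11 genes of metal binding and the acute phase, 9 rose, 1 fell and 1 was not called (9 higher and 1 lower adjusted over the list alone). Their median was 0.60 (camera adjusted p = 0.000514, adjusted p = 0.0388 with an estimated correlation). The ferritin gene Fth1 rose by 1.25 ± 0.09. Of the 64 cytosolic ribosomal protein genes, 20 rose and 44 were not called (11 higher adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.00398, adjusted p = 0.698 with an estimated correlation), and camera adjusted p = 0.0638 under quantile normalization. Rps24 was higher by 0.44 ± 0.10 and Rpl37 by 0.37 ± 0.09, the latter not called with the 2 groups fitted alone, and corticosterone replicate 4 had a list mean of 8.86 log2 CPM against 8.13 to 8.24 in the other treated libraries. Without that library 5 ribosomal protein genes were higher and 10 lower, with a median of -0.01.

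Proliferation, sterol synthesis and matrix genes moved the other way. Of the 46 genes of DNA replication and mitosis, 45 fell and 1 was not called (45 lower adjusted over the list alone). Their median was -0.98 (camera adjusted p = 6.3e-26, adjusted p = 0.00997 with an estimated correlation). Tyms, which encodes thymidylate synthase, was at -1.15 ± 0.05 and Kif20a, a kinesin of cell division, at -1.28 ± 0.06. Of the 25 genes of cholesterol synthesis, 21 fell and 4 were not called (21 lower adjusted over the list alone). Their median was -0.93 (camera adjusted p = 1.8e-16, adjusted p = 0.00997 with an estimated correlation). Cyp51, the sterol demethylase, was at -1.62 ± 0.05 and Insig1, which retains the sterol sensor in the endoplasmic reticulum, at -1.42 ± 0.06. Of the 32 extracellular matrix genes, 2 rose, 24 fell and 6 were not called (2 higher and 25 lower adjusted over the list alone). Their median was -0.54 (camera adjusted p = 6.5e-09, adjusted p = 0.0265 with an estimated correlation). Col6a2, a collagen VI chain, was at -1.26 ± 0.06, while the proteoglycan gene decorin, Dcn, went the other way at 2.76 ± 0.10. Of the 27 feedback and immediate early genes of MAP kinase signalling, 1 rose, 21 fell and 5 were not called (1 higher and 22 lower adjusted over the list alone). Their median was -0.65 (camera adjusted p = 3.5e-07, adjusted p = 0.0845 with an estimated correlation). The phosphatase gene Dusp4 was at -2.09 ± 0.12 and Phlda1 at -1.88 ± 0.12.

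Inflammatory and interferon-stimulated genes fell as lists at day 3. Of the 20 inflammatory and chemokine genes, 5 rose, 13 fell and 2 were not called (5 higher and 13 lower adjusted over the list alone). Their median was -0.67 (camera adjusted p = 0.00152, adjusted p = 0.0845 with an estimated correlation). The chemokine genes Cxcl12 and Cxcl10 were at -1.15 ± 0.04 and -1.80 ± 0.07. Of the 36 interferon-stimulated genes, 5 rose, 19 fell and 12 were not called (5 higher and 20 lower adjusted over the list alone). Their median was -0.28 (camera adjusted p = 0.0146, adjusted p = 0.386 with an estimated correlation). The guanylate-binding protein gene Gbp2 was at -0.93 ± 0.07. Class I and antigen processing genes were not called as a list, with 7 of 18 lower (6 adjusted over the list alone, median -0.12, or -0.23 without corticosterone replicate 4, camera adjusted p = 0.188). Hypoxia response and glycolysis genes were not called either, with 10 and 7 members higher and 7 and 3 lower (medians 0.19 and 0.11, camera adjusted p = 0.152 and 0.178). Of the 35 lists tested 17 were called at day 3, 9 upward and 8 downward, and 6 of these held with an estimated correlation.

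**Figure D2:**
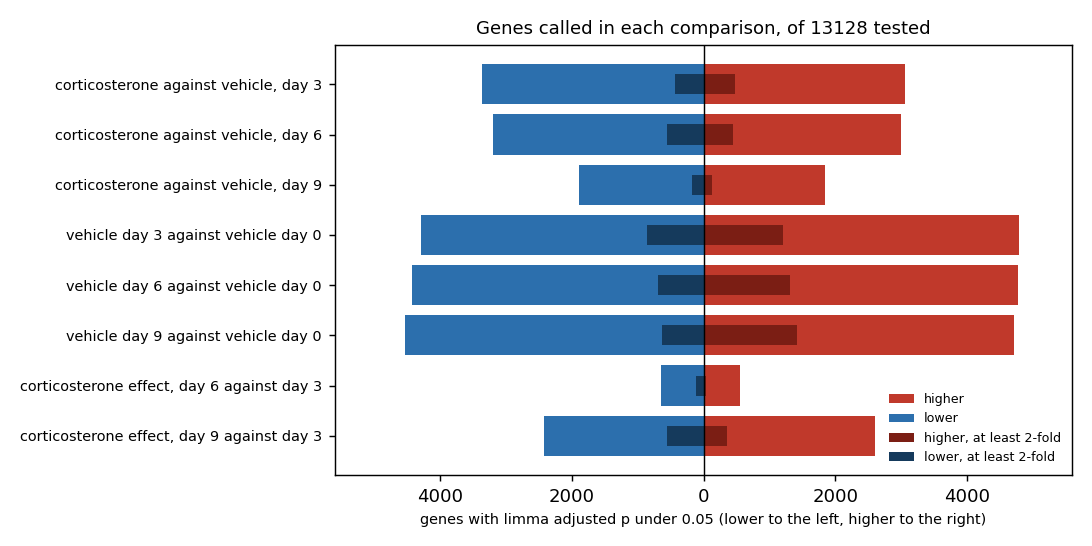
Number of genes with limma adjusted p under 0.05 in each comparison, of 13128 tested, lower to the left and higher to the right, with the darker bars for changes of at least 2-fold.

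To determine what remained or appeared 3 days after the medium with hormone had been replaced, treated and vehicle libraries of day 6 were compared. Folh1 and Zbtb16 again rose most, by 9.76 ± 0.47 and 9.12 ± 0.35, with 2 vehicle libraries of Folh1 at the lowest value of the table (6.51 and 5.79 with log2(CPM + 1)). Others were Cyp4a12a at 7.31 ± 0.29 (adjusted p = 8.9e-17, and 8.83 ± 0.29 at day 3), Aldh1a7 at 6.55 ± 0.29, the glutathione transferase gene Gsta3 at 4.89 ± 0.16 and the retinaldehyde dehydrogenase gene Aldh1a1 at 4.37 ± 0.09 (adjusted p = 1.7e-22). Aldh1a1 reached 11.36 ± 0.31 log2 CPM against 6.98 ± 0.03 in vehicle, and Kank4, Spink8 and Trim67 were still higher, by 4.88 ± 0.36, 4.75 ± 0.30 and 4.58 ± 0.10. Egln3, a prolyl hydroxylase gene of oxygen sensing, fell most within the limits, at -4.60 ± 0.15 (adjusted p = 2.2e-18). It was at 1.30 ± 0.07 log2 CPM against 5.90 ± 0.26 in vehicle and 1.41 at day 0.

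Ankrd37, a target of hypoxia-inducible factors, was at -4.48 ± 0.24, Spp1 at -4.06 ± 0.32 and Vcam1 at -3.38 ± 0.15 at day 6. The cornified envelope genes Sprr1a and Sprr2g were at -3.82 ± 0.18 and -3.10 ± 0.18, the ETS factor gene Etv4 at -3.65 ± 0.22, Olfml3 at -3.16 ± 0.21, Tnfaip2 at -3.15 ± 0.29 and the cyclic GMP-dependent kinase gene Prkg2 at -3.06 ± 0.16. In limma 3002 genes were higher and 3192 lower (47.2% of those tested), 441 and 549 of them at least 2-fold. The Sprr, Gsta and Cyp4a genes belong to families of close paralogs, among which reads may not be fully separated.

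Hypoxia response and glycolysis genes, not called as lists at day 3, fell at day 6. Of the 22 hypoxia response genes, 1 rose, 18 fell and 3 were not called (1 higher and 18 lower adjusted over the list alone). Their median was -0.87 (camera adjusted p = 8.9e-10, adjusted p = 0.0678 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase, was at -1.81 ± 0.08. Of the 20 glycolysis genes, 3 rose, 16 fell and 1 was not called (3 higher and 16 lower adjusted over the list alone). Their median was -1.03 (camera adjusted p = 1.7e-08, adjusted p = 0.0955 with an estimated correlation). Pkm, the muscle-type pyruvate kinase gene, was at -1.48 ± 0.05 and Ldha, lactate dehydrogenase A, at -2.24 ± 0.08. In contrast, of the 65 oxidative phosphorylation genes, 64 rose and 1 was not called (64 higher adjusted over the list alone). Their median was 0.64 (camera adjusted p = 7.7e-22, adjusted p = 0.208 with an estimated correlation). Cycs and Cyc1 were higher by 0.98 ± 0.07 and 0.88 ± 0.07. Of the 22 tricarboxylic acid cycle genes, 21 rose and 1 was not called (22 higher adjusted over the list alone). Their median was 0.61 (camera adjusted p = 3.8e-14, adjusted p = 0.00659 with an estimated correlation). Pdha1 was higher by 0.90 ± 0.04 and Idh3a by 0.72 ± 0.04, and corticosterone replicate 6 had a list mean of 7.41 log2 CPM against 7.50 to 7.52 in the other treated libraries. Of the 23 fatty acid oxidation genes, 18 rose, 1 fell and 4 were not called (18 higher and 1 lower adjusted over the list alone). Their median was 0.42 (camera adjusted p = 5.8e-08, adjusted p = 0.0845 with an estimated correlation). Etfdh rose by 0.79 ± 0.04 and Ppargc1a, a coactivator of mitochondrial gene expression, by 1.73 ± 0.12.

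Of the 11 mitochondrially encoded transcripts, 10 rose and 1 was not called (11 higher adjusted over the list alone). Their median was 0.65 (camera adjusted p = 2.1e-07, adjusted p = 0.0955 with an estimated correlation), and a median of 0.05 that was not called under quantile normalization (camera adjusted p = 0.589). The examples mt-Co1 and mt-Nd4, a subunit of the first respiratory complex, were higher by 0.74 ± 0.05 and 0.81 ± 0.07, calls that ended under quantile normalization (0 and 0.14). At day 6, of the 29 receptor target genes, 22 rose, 2 fell and 5 were not called (22 higher and 2 lower adjusted over the list alone). Their median was 1.33 (camera adjusted p = 4.6e-11, adjusted p = 0.0845 with an estimated correlation). Cavin2, a coat protein of caveolae, rose by 1.80 ± 0.07. Corticosterone replicate 6 stood apart on this list, with a mean of 5.01 log2 CPM against 5.66 to 5.71 in the other 3 treated libraries and Sgk1 at 7.20 against 9.05 to 9.42, and without it 23 members were higher, with a median of 1.54. Here, of the 46 cell cycle genes, 46 fell (46 lower adjusted over the list alone). Their median was -1.08 (camera adjusted p = 1.2e-29, adjusted p = 0.00659 with an estimated correlation). The thymidine kinase gene Tk1 was at -1.27 ± 0.06 and Kif20a at -1.26 ± 0.06. By day 6, of the 25 cholesterol synthesis genes, 1 rose, 11 fell and 13 were not called (1 higher and 12 lower adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.00632, adjusted p = 0.323 with an estimated correlation). Cyp51 was at -0.49 ± 0.05 and the sterol carrier gene Stard4 at -0.74 ± 0.06.

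Matrix, signalling, interferon and inflammatory genes remained lower as lists, and class I genes fell. Of the 32 extracellular matrix genes, 3 rose, 24 fell and 5 were not called (3 higher and 25 lower adjusted over the list alone). Their median was -0.47 (camera adjusted p = 3.9e-08, adjusted p = 0.0533 with an estimated correlation). Col6a1, a collagen VI chain, was at -0.74 ± 0.04 and the lysyl oxidase gene Loxl2 at -1.18 ± 0.06. Of the 27 MAP kinase feedback genes, 3 rose, 18 fell and 6 were not called (3 higher and 18 lower adjusted over the list alone). Their median was -0.62 (camera adjusted p = 4.1e-05, adjusted p = 0.188 with an estimated correlation). Fosl1, of the AP-1 family, was at -2.15 ± 0.12. Of the 36 interferon-stimulated genes, 3 rose, 23 fell and 10 were not called (3 higher and 23 lower adjusted over the list alone). Their median was -0.45 (camera adjusted p = 6.5e-05, adjusted p = 0.218 with an estimated correlation). Cmpk2, a mitochondrial nucleotide kinase induced by interferon, was at -1.73 ± 0.09 and Rsad2 at -2.96 ± 0.18. Of the 20 inflammatory genes, 2 rose, 12 fell and 6 were not called (2 higher and 12 lower adjusted over the list alone). Their median was -0.64 (camera adjusted p = 9.5e-05, adjusted p = 0.0612 with an estimated correlation). Cxcl10 and the monocyte chemokine gene Ccl2 were at -1.96 ± 0.07 and -2.45 ± 0.09. Of the 18 genes of major histocompatibility complex class I and antigen processing, 11 fell and 7 were not called (13 lower adjusted over the list alone). Their median was -0.45 (camera adjusted p = 0.000720, adjusted p = 0.117 with an estimated correlation). H2-Q4 was at -1.27 ± 0.08 and H2-T23 at -1.36 ± 0.09, both from a family of close paralogs. At day 6 16 of the 35 lists were called, 6 upward and 10 downward, of which 2 held with an estimated correlation.

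**Figure D3:**
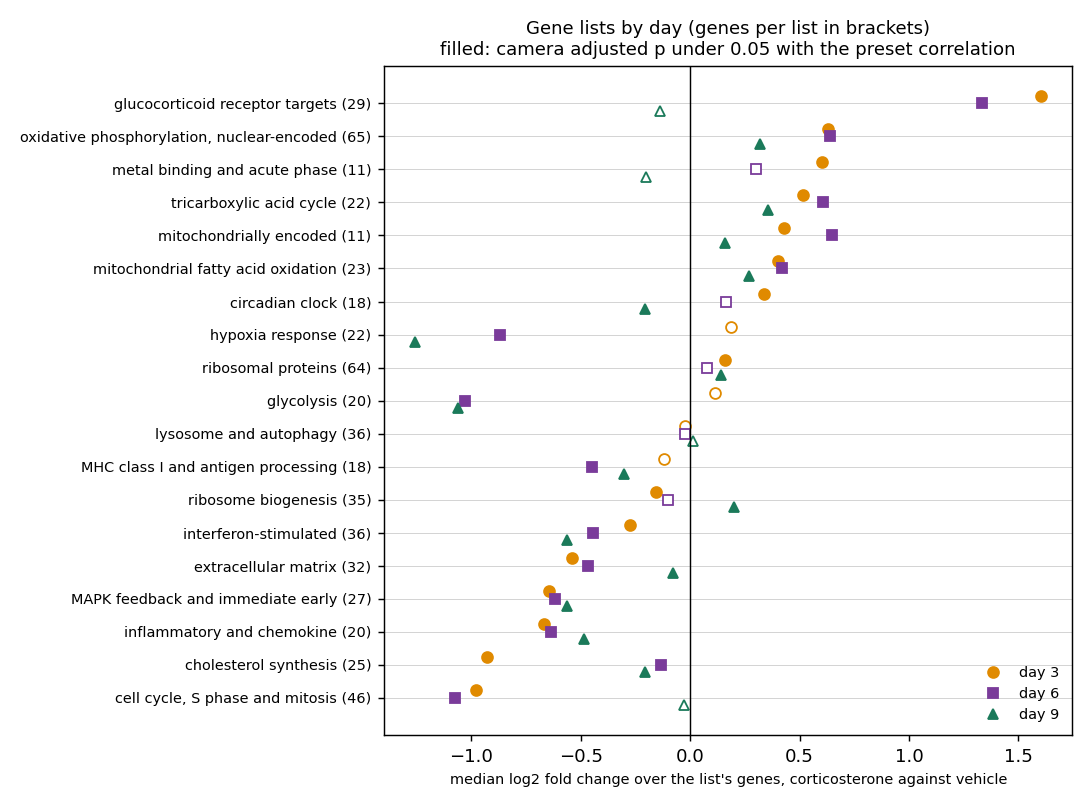
Median log2 fold change, corticosterone against vehicle, over the genes of 19 lists at days 3, 6 and 9, with the number of measured genes in brackets and filled symbols for lists with camera adjusted p under 0.05 at the preset correlation.

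To determine what was left 6 days after the treatment, treated and vehicle libraries of day 9 were compared. Within the ranking limits the largest rises were in Kank4 at 3.27 ± 0.36 (adjusted p = 1.2e-07), Eva1a at 2.76 ± 0.40, Gsta3 at 2.32 ± 0.16 and Aldh1a1 at 2.29 ± 0.09 (adjusted p = 1.4e-15). Others were Coro2a, a coronin, at 2.18 ± 0.42, the keratin genes Krt7 and Krt8 at 1.96 ± 0.32 and 1.62 ± 0.27 and Actr3b at 1.96 ± 0.16. Klhl13 was at 1.74 ± 0.38 and the selenium transport gene Selenop at 1.70 ± 0.10. Outside the limits Folh1 (5.48), Zbtb16 (4.66), Aldh1a7 (3.94) and Cyp4a12a (3.43) rose more than Kank4. Aire fell most within them, at -5.30 ± 0.37 (adjusted p = 4.0e-11, -1.95 with log2(CPM + 5)). It stood at -1.29 ± 0.82 log2 CPM against 4.00 ± 0.12 in vehicle, up from -2.34 at day 0.

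Among the other falls at day 9 were the mitochondrial adenylate kinase gene Ak4 at -3.28 ± 0.61, Egln3 at -3.12 ± 0.15, the vasodilator peptide gene Adm at -2.92 ± 0.35, Ankrd37 at -2.41 ± 0.24 and the mitophagy receptor gene Bnip3 at -2.33 ± 0.13. Nlrp10, of the NLR family, was at -3.42 ± 0.24, the vesicle priming gene Unc13a at -2.40 ± 0.13, Cables1 at -2.36 ± 0.25 and Lrp2bp at -2.22 ± 0.28. In limma 1849 genes were higher and 1887 lower (28.5% of those tested), 123 and 173 of them at least 2-fold. Krt8 has many processed pseudogenes, whose reads may not be fully separated from its own.

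The fall in hypoxia response and glycolysis genes was the clearest list result at day 9. Of the 22 hypoxia response genes, 20 fell and 2 were not called (20 lower adjusted over the list alone). Their median was -1.26 (camera adjusted p = 2.1e-27, adjusted p = 0.00236 with an estimated correlation). Slc2a1, which encodes the main glucose transporter of epithelial cells, was at -1.28 ± 0.05 and the oxygen sensor gene Egln1 at -1.80 ± 0.08. Of the 20 glycolysis genes, 1 rose, 18 fell and 1 was not called (1 higher and 18 lower adjusted over the list alone). Their median was -1.06 (camera adjusted p = 1.8e-23, adjusted p = 0.00546 with an estimated correlation). Pkm was at -1.06 ± 0.05. Of the 65 oxidative phosphorylation genes, 40 rose, 1 fell and 24 were not called (49 higher and 1 lower adjusted over the list alone). Their median was 0.32 (camera adjusted p = 2.7e-15, adjusted p = 0.254 with an estimated correlation). Ndufa10, of the first respiratory complex, rose by 0.50 ± 0.06 and Uqcrc1, of the cytochrome bc1 complex, by 0.46 ± 0.05. Of the 22 tricarboxylic acid cycle genes, 20 rose, 1 fell and 1 was not called (20 higher and 1 lower adjusted over the list alone). Their median was 0.35 (camera adjusted p = 2.6e-13, adjusted p = 0.00546 with an estimated correlation). Idh3a was higher by 0.56 ± 0.04 and the citrate synthase gene Cs by 0.48 ± 0.05. Of the 23 fatty acid oxidation genes, 14 rose and 9 were not called (15 higher and 1 lower adjusted over the list alone). Their median was 0.27 (camera adjusted p = 8.1e-07, adjusted p = 0.0940 with an estimated correlation). Etfdh and the acyl-CoA dehydrogenase gene Acads were higher by 0.40 ± 0.04 and 0.45 ± 0.06.

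Of the 35 ribosome biogenesis genes, 17 rose, 1 fell and 17 were not called (18 higher and 1 lower adjusted over the list alone). Their median was 0.20 (camera adjusted p = 1.9e-06, adjusted p = 0.0547 with an estimated correlation). Bysl, a processing factor of the small subunit, rose by 0.56 ± 0.06 and the nucleolin gene Ncl by 0.31 ± 0.04. Of the 27 MAP kinase feedback genes, 21 fell and 6 were not called (22 lower adjusted over the list alone). Their median was -0.56 (camera adjusted p = 2.1e-11, adjusted p = 0.0315 with an estimated correlation). The phosphatase gene Dusp5 was at -1.17 ± 0.09 and the growth factor gene Hbegf at -0.56 ± 0.06. Of the 36 interferon-stimulated genes, 1 rose, 26 fell and 9 were not called (1 higher and 27 lower adjusted over the list alone). Their median was -0.57 (camera adjusted p = 2.9e-11, adjusted p = 0.0422 with an estimated correlation). Oasl2, of the oligoadenylate synthase-like family, was at -1.11 ± 0.09 and Cmpk2 at -1.01 ± 0.09. Of the 20 inflammatory genes, 1 rose, 13 fell and 6 were not called (1 higher and 14 lower adjusted over the list alone). Their median was -0.49 (camera adjusted p = 5.0e-07, adjusted p = 0.00849 with an estimated correlation). Ccl2 was at -1.21 ± 0.09 and Vcam1 at -1.33 ± 0.15. Of the 18 class I and antigen processing genes, 10 fell and 8 were not called (10 lower adjusted over the list alone). Their median was -0.30 (camera adjusted p = 4.6e-05, adjusted p = 0.0547 with an estimated correlation). H2-K1, a classical class I gene, was at -1.09 ± 0.06 and H2-Q4 at -0.90 ± 0.08.

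Of the 25 cholesterol synthesis genes, 12 fell and 13 were not called (1 higher and 13 lower adjusted over the list alone). Their median was -0.21 (camera adjusted p = 4.6e-05, adjusted p = 0.154 with an estimated correlation). Insig1 was at -0.58 ± 0.06 and Stard4 at -0.63 ± 0.06. Of the 18 clock genes, 1 rose, 10 fell and 7 were not called (1 higher and 13 lower adjusted over the list alone). Their median was -0.21 (camera adjusted p = 4.6e-05, adjusted p = 0.04997 with an estimated correlation). Bhlhe40, a repressor in the clock, was at -1.205 ± 0.08 and Per3 at -0.73 ± 0.05. Receptor targets were no longer called as a list, with 6 higher, 10 lower and 13 not called (8 and 12 adjusted over the list alone), median -0.14, mean 0.20 and a downward test at camera adjusted p = 0.697. Zbtb16 stayed higher (4.66 ± 0.35). Cell cycle genes were not called either, with 5 higher and 5 lower of 46 (median -0.03, camera adjusted p = 0.697). Of the 35 lists 19 were called at day 9, 8 upward and 11 downward, and 7 of these held with an estimated correlation.

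To determine how much of each library came from the mitochondrial genome, the share of CPM on mitochondrially encoded genes was compared. At day 3 it was 7.11% ± 0.36 (SD, n = 4) with corticosterone and 5.31% ± 0.11 with vehicle, at day 6 8.61% ± 0.41 and 5.64% ± 0.19, and at day 9 6.62% ± 0.38 and 5.83% ± 0.20, against 3.28% ± 0.05 before treatment. On each day all 4 treated libraries lay above all 4 vehicle libraries (exact permutation test, 2-sided, p = 0.0286 and adjusted p = 0.0286 over the 3 days, the smallest p that 70 splits allow).

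To determine which effects differed between days, the corticosterone effect at day 6 and at day 9 was tested against that at day 3. Within the ranking limits, the effect moved down most between days 3 and 6 for Adm at -4.78 ± 0.49 (difference of log2 fold changes ± SE), Egln3 at -4.15 ± 0.21, Ankrd37 at -3.80 ± 0.33, Bnip3 at -2.79 ± 0.18 and Pdk1 at -2.59 ± 0.17. Adm had risen by 4.35 ± 0.35 at day 3 and was not called at day 6 (-0.42). The effect moved up for Npr3 at 1.46 ± 0.12, the receptor phosphatase gene Ptprz1 at 1.36 ± 0.16, the transcription factor gene Sox8 at 1.33 ± 0.17 and Idi1, of sterol synthesis, at 1.29 ± 0.11. Calcrl, a receptor subunit for adrenomedullin, was at 1.51 ± 0.47 (adjusted p = 0.0426), a call that ended with the compared groups alone and without most single libraries, at values from 1.33 to 1.52. In limma 553 differences were positive and 643 negative between days 3 and 6, against 2604 and 2424 between days 3 and 9, or 9.11% and 38.3% of genes.

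Between days 3 and 9 the effect moved down for Adm at -7.27 ± 0.49, Sgk1 at -6.90 ± 0.40, Lcn2 at -5.05 ± 0.33, Trim67 at -4.40 ± 0.14 and Ifi207 at -4.32 ± 0.21. It moved up for the water channel gene Aqp5 at 3.501 ± 0.28, Siglecg at 3.12 ± 0.38, Cd300lb at 3.02 ± 0.30, Spp1 at 2.80 ± 0.45 and Samd5 at 2.79 ± 0.26, with Spp1 not called at log2(CPM + 5) (0.33, adjusted p = 0.0518). For cholesterol synthesis genes the difference was positive in 22 of 25 at both later days (medians 0.70 and 0.72, camera adjusted p = 1.0e-33 and 4.3e-14, adjusted p = 0.000257 and 0.0115 with an estimated correlation). For hypoxia response genes it was negative in 17 of 22 at day 6 and in 19 at day 9 (medians -0.90 and -1.63, camera adjusted p = 5.5e-33 and 2.1e-16, adjusted p = 0.000401 and 0.0115 with an estimated correlation). Glycolysis genes followed, with 15 and 18 of 20 negative (medians -1.15 and -1.14, camera adjusted p = 1.3e-32 and 3.5e-16, adjusted p = 0.000769 and 0.01499 with an estimated correlation).

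By day 9 the effect on cell cycle genes had moved up in 43 of 46 (median 0.92, camera adjusted p = 2.5e-24, adjusted p = 0.0115 with an estimated correlation) and that on receptor targets down in 26 of 29 (median -2.06, camera adjusted p = 4.9e-18, adjusted p = 0.01499 with an estimated correlation). Clock genes moved down in 10 of 18 at day 6 and in 13 at day 9 (medians -0.37 and -0.72, camera adjusted p = 8.7e-08 and 7.3e-08, adjusted p = 0.0108 and 0.0115 with an estimated correlation). Oxidative phosphorylation genes showed no difference between days 3 and 6 that passed the test (0 positive and 0 negative of 65, median 0.00045, camera adjusted p = 0.637), and between days 3 and 9 the effect was smaller in 30 (median -0.34, camera adjusted p = 2.8e-06, adjusted p = 0.590 with an estimated correlation). Both rest on a day 3 median that was 0.48 without corticosterone replicate 4. Of the 35 lists 18 were called between days 3 and 6, 4 of them with an estimated correlation, and 14 between days 3 and 9, 7 of them with an estimated correlation.

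**Figure D4:**
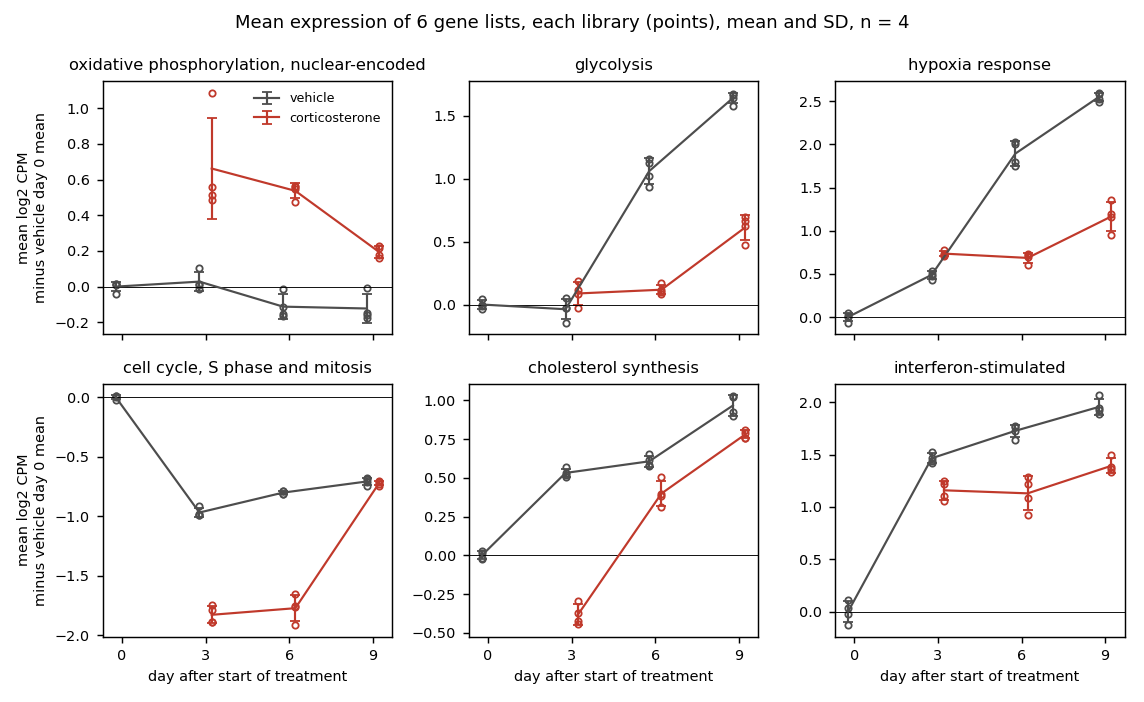
Mean log2 CPM over the genes of 6 lists, minus the mean of vehicle day 0, by day, with libraries as points and lines through means ± SD (n = 4), vehicle in grey and corticosterone in red. Vehicle libraries climbed in hypoxia response and glycolysis genes from day 3 to day 9, and the separate treated point in oxidative phosphorylation at day 3 is replicate 4.

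To determine how many genes kept their day 3 change, calls were compared between days. Of the 3065 genes higher at day 3, 2127 (69.4%) were also higher at day 6 and 763 (24.9%) at day 9, against 701 and 432 for independent calls. Of the 3364 genes lower at day 3, 2295 (68.2%) were also lower at day 6 and 779 (23.2%) at day 9, against 818 and 484 for independent calls. On all 3 days 710 genes were higher and 706 lower. Calls in the opposite direction numbered 56 and 49 at day 6 and 381 and 382 at day 9, for genes higher and lower at day 3. Over the genes called at day 3 the median share of the log2 fold change kept was 0.825 at day 6 and 0.105 at day 9. Across all genes the log2 fold changes correlated at r = 0.824 between days 3 and 6, 0.345 between days 3 and 9 and 0.565 between days 6 and 9, where genes are not independent replicates. Aldh1a1 (4.39, 4.37 and 2.29), Kank4 (5.51, 4.88 and 3.27) and Folh1 (9.47, 9.76 and 5.48) were among the genes higher on all 3 days, and Vcam1 (-3.09, -3.38 and -1.33) was among those lower.

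To determine what time in confluent culture changed without the hormone, vehicle libraries of days 3, 6 and 9 were compared with day 0. By day 9 Ak4 had risen by 7.81 ± 0.61, from -2.56 ± 1.48 to 5.25 ± 0.13 log2 CPM (4.98 with log2(CPM + 1)), Egln3 by 5.91 ± 0.15 and Adm by 4.56 ± 0.35, all genes of the response to low oxygen. Other large rises were in Steap4 at 6.59 ± 0.15, the complement gene C3 at 5.23 ± 0.17, Kbtbd11 at 5.07 ± 0.15, the sodium channel gene Scn3a at 4.95 ± 0.19, Wfdc1 at 4.76 ± 0.14, the steroid reductase gene Srd5a2 at 4.67 ± 0.12, and Ifi207 at 4.58 ± 0.15. Cftr, the chloride channel gene, was at -3.79 ± 0.10, Lce1g at -4.64 ± 0.35, S100a7a at -3.91 ± 0.21, Pcdh18 at -3.86 ± 0.26 and Ccdc80 at -3.85 ± 0.13. Siglecg was at -3.84 ± 0.27, Kcnip1 at -3.29 ± 0.15, the activin subunit gene Inhba at -3.21 ± 0.16, its antagonist follistatin, Fst, at -2.94 ± 0.20 and Tnfrsf21 at -3.21 ± 0.09.

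At day 3 the largest vehicle rises within the ranking limits were in Wfdc1 at 4.95 ± 0.14, Scn3a at 4.36 ± 0.19, Npas4 at 4.09 ± 0.19, Iigp1 at 3.94 ± 0.19 and Atp1b2 at 3.89 ± 0.22. The largest falls within them were in S100a7a at -4.75 ± 0.21, Sprr1a at -4.12 ± 0.18, the cyclin gene Ccnd1 at -3.98 ± 0.14, Sprr2g at -3.95 ± 0.18 and Kcnip1 at -3.38 ± 0.15. At day 6, within the same limits, Steap4 (6.23 ± 0.15), Wfdc1 (5.16 ± 0.14), Scn3a (4.78 ± 0.19), Egln3 (4.49 ± 0.15) and C3 (4.45 ± 0.17) had risen most and S100a7a (-4.22 ± 0.21), Pcdh18 (-3.57 ± 0.26), Inhba (-3.51 ± 0.16), Kcnip1 (-3.44 ± 0.15) and Siglecg (-3.42 ± 0.27) had fallen most. In limma 4789 genes were higher and 4294 lower at day 3 (69.2% of those tested), 4773 and 4424 at day 6 (70.1%) and 4708 and 4537 at day 9 (70.4%), and 1417 of the higher and 631 of the lower genes at day 9 changed at least 2-fold. The 3 vehicle comparisons share the day 0 libraries and so are not independent of each other.

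Gene lists moved widely over the vehicle course. Of the 22 hypoxia response genes from day 0 to day 9, 21 rose and 1 was not called (21 higher adjusted over the list alone). Their median was 2.35 (camera adjusted p = 2.0e-13, adjusted p = 0.0330 with an estimated correlation). Slc2a1 was higher by 2.53 ± 0.05 and the stress gene Ndrg1 by 2.50 ± 0.06. Of the 20 glycolysis genes, 19 rose and 1 was not called (19 higher adjusted over the list alone). Their median was 1.47 (camera adjusted p = 6.8e-11, adjusted p = 0.0413 with an estimated correlation). Gpi1, of glucose phosphate isomerase, rose by 2.16 ± 0.07. At day 3 only 8 of these 20 were higher and 7 were lower (8 and 7 adjusted over the list alone, median 0.10). Of the 36 interferon-stimulated genes, 36 rose (36 higher adjusted over the list alone). Their median was 1.69 (camera adjusted p = 2.1e-15, adjusted p = 0.0330 with an estimated correlation). Oasl2 rose by 3.28 ± 0.09 and Ifit1 by 2.88 ± 0.08. Of the 18 class I and antigen processing genes, 13 rose and 5 were not called (13 higher adjusted over the list alone). Their median was 1.204 (camera adjusted p = 4.0e-05, adjusted p = 0.0413 with an estimated correlation). H2-Q4 rose by 2.27 ± 0.08 and H2-K1 by 1.70 ± 0.06. Of the 36 lysosome and autophagy genes, 31 rose, 2 fell and 3 were not called (31 higher and 2 lower adjusted over the list alone). Their median was 0.55 (camera adjusted p = 1.3e-07, adjusted p = 0.0413 with an estimated correlation). The lysosomal enzyme genes Ctsa and Naglu rose by 1.502 ± 0.05 and 1.43 ± 0.06. Of the 25 cholesterol synthesis genes, 23 rose, 1 fell and 1 was not called (23 higher and 1 lower adjusted over the list alone). Their median was 0.98 (camera adjusted p = 4.2e-09, adjusted p = 0.0413 with an estimated correlation). Insig1 rose by 2.48 ± 0.06 and Sqle, a squalene epoxidase, by 1.66 ± 0.05.

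Of the 18 clock genes, 16 rose and 2 fell (16 higher and 2 lower adjusted over the list alone). Their median was 0.63 (camera adjusted p = 4.0e-05, adjusted p = 0.0413 with an estimated correlation). Bhlhe40 rose by 3.28 ± 0.08 and Per3 by 1.40 ± 0.05. Of the 27 MAP kinase feedback genes, 20 rose, 3 fell and 4 were not called (20 higher and 3 lower adjusted over the list alone). Their median was 1.33 (camera adjusted p = 4.1e-05, adjusted p = 0.150 with an estimated correlation). The immediate early genes Fos and Egr1 rose by 3.52 ± 0.15 and 2.19 ± 0.10. Of the 11 mitochondrially encoded transcripts, 10 rose and 1 fell (10 higher and 1 lower adjusted over the list alone). Their median was 0.84 (camera adjusted p = 0.000628, adjusted p = 0.226 with an estimated correlation), and a median of 0.53 under quantile normalization, still called. The example mt-Co1 rose by 0.84 ± 0.05 (0 and not called under quantile normalization) and mt-Cytb by 0.89 ± 0.06. Of the 64 ribosomal protein genes, 64 fell (64 lower adjusted over the list alone). Their median was -0.95 (camera adjusted p = 1.1e-16, adjusted p = 0.241 with an estimated correlation). Rplp0 was at -1.05 ± 0.06 and Rps12 at -1.37 ± 0.10. Of the 35 ribosome biogenesis genes, 33 fell and 2 were not called (33 lower adjusted over the list alone). Their median was -1.07 (camera adjusted p = 6.7e-16, adjusted p = 0.00713 with an estimated correlation). Ncl was at -1.66 ± 0.04 and Rrp12 at -1.41 ± 0.05. Of the 46 cell cycle genes, 5 rose, 37 fell and 4 were not called (5 higher and 37 lower adjusted over the list alone). Their median was -0.79 (camera adjusted p = 2.6e-08, adjusted p = 0.123 with an estimated correlation). Rrm2, of ribonucleotide reductase, was at -1.63 ± 0.06 and Kif20a at -1.58 ± 0.06. Of the 35 lists 20 were called between vehicle days 0 and 9, 14 upward and 6 downward, and 10 of these held with an estimated correlation.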

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

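The tests on exchanged cultures, remaining hormone, transcript loss, library scaling, the removal of a length trend and the left-out library were chosen only after the results they concern were seen. The first pattern was that 22 of 29 receptor targets were still higher at day 6, 3 days after the medium change, and no longer called as a list at day 9. Treated day 6 libraries made from day 3 cultures are argued against by 3975 genes (30.3%) that differed between treated libraries of the 2 days in limma. Transcripts made before day 3 and lost at a constant rate would have left the 24 targets higher at day 3 at a median of 1.15 on day 9, not -0.10, and the median difference of -1.18 (95% bootstrap interval -1.78 to -0.70) argues against such carry-over as the whole cause. Hormone left in the wells could also keep targets high, and it cannot be told apart from a lasting response, because a median 0.792 of the day 3 effect was kept (0.558 to 0.909) and no hormone level was used here. A response of the cells that outlasts the hormone stays open as an untested hypothesis.

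The second pattern was the lower level of hypoxia response and glycolysis genes at days 6 and 9, while vehicle cultures climbed in them after day 3. Library scaling is argued against, since the day 9 median over the 40 members was -1.15 as tested and -1.07 (-1.33 to -0.82) under quantile normalization, and the 2 list medians under median centring were -1.25 and -1.059 at day 9 and -0.85 and -1.01 at day 6. A slower time course of treated cultures was tested by members over 2 standard errors below every vehicle time point, 1 of 40 (2.5%) at day 9, but vehicle had risen by list medians of 2.35 and 1.47, more than the falls of 1.26 and 1.061, so a direct effect would give that too and the test decides nothing. At day 6 4 of 40 members (10%) lay so, between the bounds set beforehand, so a lag cannot be told apart from an added effect of the hormone, and 52.7% of all called genes lay outside the vehicle range (8.94% at day 9). Both explanations stay open.

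The third pattern was the higher level of 87 genes of oxidative phosphorylation and the tricarboxylic acid cycle at days 3 and 6, with median transcripts of 969 and 2608 bases against 3157 over all genes. With a trend of expression on transcript length removed from each library, the median over both went from 0.61 to 0.48 (0.43 to 0.52) at day 3, more in the first list (0.63 to 0.47) than the second (0.51 to 0.50), and from 0.63 to 0.58 (0.55 to 0.61) at day 6, so length bias is argued against as the whole cause. The oxidative phosphorylation call then held with an estimated correlation, at adjusted p = 0.0207 and 0.0122, while the ribosomal protein call at day 3 ended (median 0.16 before and 0.01 after). Corticosterone day 3 replicate 4, with the largest deviations, is argued against as the source, since 87 of 87 members were still higher without it, at a median of 0.47. A hormone effect stays a candidate explanation, found and tested on the same libraries.

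Among the 35 splits of the 8 libraries of a comparison, only 1, the real one, gave as many genes at day 3 (6429, highest other 1762), day 6 (6194, 981) and day 9 (3736, 11). The same held for vehicle days 3 (9083, 4), 6 (9197, 2) and 9 (9245, 2) against day 0. As many or more lists came from 3 of 35 splits at day 3 (17, highest other 18), 5 at day 6 (16, 18), 1 at day 9 (19, 18) and 5 for vehicle day 9 (20, 21). By the preset rule chance fits all lists but day 9, yet mixed splits hold group differences, so no count tests chance. Leave-one-out fits (18 to 19) close the day 9 margin of 1 list. Of 100 random splits only the real one reached the count for the change of effect from day 3 to day 6 (1203, highest other 595) and to day 9 (5032, 2857), on values with additive effects removed, again the least possible. The real one alone also reached the shared calls at day 6 (4422, 822) and day 9 (1542, 0), which says nothing of sharing beyond independent calls.

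Of 628 groups of 4 values (named genes, list means, mitochondrial share and deviations) 50, or 7.96%, held a library whose gap to the next one exceeded Dixon's critical share of the range, while chance gives about 1 in 20. Corticosterone day 6 replicate 6 held 15 of them, in most cases with a smaller response than its group, and corticosterone day 3 replicate 4 held 11. Values are log2 CPM, for these 2 followed by the median of the other 3 libraries. In corticosterone day 6 replicate 6 they were Aldh1a7 (4.27, 5.49), Bnip3 (5.65, 6.13), Cavin2 (6.51, 6.87), Cycs (7.61, 7.78) and Cyp4a12a (4.70, 5.94). Also in this library were Fkbp5 (8.32, 9.16), Folh1 (6.12, 6.94), H2-T23 (2.95, 3.14), Pdha1 (7.88, 8.03) and Sgk1 (7.20, 9.25). Further there were Tsc22d3 (6.41, 7.41), Vcam1 (3.58, 2.74), the tricarboxylic acid cycle mean (7.41, 7.50), the receptor target mean (5.01, 5.70) and the metal binding mean (7.02, 7.27). In corticosterone day 3 replicate 4 they were Cxcl10 (3.32, 3.02), Fth1 (12.46, 11.95), Klf9 (6.77, 7.16), Ptprz1 (1.88, 2.46) and Rpl37 (8.84, 8.22). Also in this library were Sgk1 (9.19, 9.45), the oxidative phosphorylation mean (7.70, 7.13), the tricarboxylic acid cycle mean (7.60, 7.44), the ribosomal protein mean (8.86, 8.19) and the ribosome biogenesis mean (5.75, 5.60). Single values lay apart in vehicle day 3 replicate 3 (Atp1b2 3.25, Cyc1 7.69 and the cell cycle mean 6.2999), vehicle day 3 replicate 6 (Etfdh 6.67, Pdk1 5.46 and Rpl37 7.92), vehicle day 0 replicate 4 (Ak4 -0.37 and Scn3a -1.76) and corticosterone day 9 replicate 3 (Coro2a 3.11 and Nr3c2 3.28). Others lay in vehicle day 9 replicate 6 (Cs 8.43), vehicle day 0 replicate 6 (Ctsa 7.97 and Lce1g 3.95), corticosterone day 9 replicate 4 (Eva1a 2.28 and the MAP kinase feedback mean 4.87) and vehicle day 3 replicate 5 (Sprr2g 5.08). Further ones were in vehicle day 6 replicate 5 (the receptor target mean 3.86), vehicle day 6 replicate 4 (Aldh1a1 7.02), vehicle day 9 replicate 4 (Egln1 8.49) and vehicle day 6 replicate 3 (Hsd11b2 2.10). Then came corticosterone day 6 replicate 1 (Kif20a 5.55). The root mean square deviation from the group means lay apart in corticosterone day 3 replicate 4 (0.305), vehicle day 9 replicate 6 (0.152), vehicle day 3 replicate 5 (0.11) and vehicle day 6 replicate 5 (0.128).

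The corticosterone effect at day 6 differed from that at day 3, by a test of the difference itself in limma, for 1196 genes, 18 lists and 70 of 147 genes named in the report (highest adjusted p = 0.0494). The difference was negative for Ak4 (-5.61), Adm (-4.78), Aire (-4.45), Egln3 (-4.15), Ankrd37 (-3.80), Cables1 (-3.23), Bnip3 (-2.79), Pdk1 (-2.59), Nlrp10 (-2.40), Lrp2bp (-1.92), Ldha (-1.78) and Srd5a2 (-1.78). Next were Npas4 (-1.68), Lcn2 (-1.66), Cyp4a12a (-1.52), Dcn (-1.51), Kbtbd11 (-1.48), Gpi1 (-1.45), P4ha1 (-1.44), Etv4 (-1.42), Egln1 (-1.40), H2-T23 (-1.38), Prkg2 (-1.37) and Sprr1a (-1.37). Then came Ifi207 (-1.23), Sprr2g (-1.21), Pkm (-1.15), Unc13a (-1.04), Per3 (-0.997), Scn3a (-0.92), Cmpk2 (-0.92), Slc2a1 (-0.85), Oasl2 (-0.82), C3 (-0.79), Kcnip1 (-0.74) and Loxl2 (-0.72). Smaller ones were those of Mt2 (-0.70), Per2 (-0.60), Ccl2 (-0.56), H2-K1 (-0.55), Fosl1 (-0.55), H2-Q4 (-0.54), Ifit1 (-0.47), Dusp5 (-0.42), Bhlhe40 (-0.38), Per1 (-0.36), Tk1 (-0.35) and Itgb6 (-0.34). The smallest was that of Rrm2 (-0.27). It was positive for Calcrl (1.51), Npr3 (1.46), Ptprz1 (1.36), Sox8 (1.33), Idi1 (1.29), Insig1 (1.29), Cyp51 (1.13), Inhba (1.13), Cdh6 (0.93), Hsd11b2 (0.91), Sqle (0.83) and Cftr (0.72). Then came Selenop (0.62), Stard4 (0.57), mt-Nd4 (0.43), Col6a2 (0.30), Bysl (0.29), Etfdh (0.28), Cs (0.24), Rrp12 (0.24) and Cxcl12 (0.21).

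At day 9 the effect differed from that at day 3 for 5028 genes, 14 lists and 113 of the named genes (highest adjusted p = 0.0379). Negative differences were those of Adm (-7.27), Sgk1 (-6.90), Cyp4a12a (-5.40), Aire (-5.09), Lcn2 (-5.05), Trim67 (-4.40), Ifi207 (-4.32), Igfbp4 (-4.27), Zbtb16 (-4.19), Folh1 (-3.99), Cables1 (-3.43) and Bnip3 (-3.17). Next came Aldh1a7 (-3.00), Unc13a (-2.97), Ak4 (-2.81), Egln3 (-2.68), Per1 (-2.36), Tsc22d3 (-2.33), Fkbp5 (-2.30), Kank4 (-2.24), Spink8 (-2.15), Dcn (-2.13), Pdk1 (-2.11) and Aldh1a1 (-2.09). Then followed Pdk4 (-2.08), Egln1 (-1.98), Gsta3 (-1.97), Eva1a (-1.92), Klf9 (-1.79), C3 (-1.73), Ankrd37 (-1.72), Gpi1 (-1.59), Mt2 (-1.57), Per2 (-1.57), Ndrg1 (-1.54) and Slc2a1 (-1.46). Lesser ones were Lrp2bp (-1.46), H2-K1 (-1.19), Kcnip1 (-1.09), Scn3a (-1.04), Ldha (-1.03), P4ha1 (-1.001), Nlrp10 (-0.99), Fth1 (-0.96), Bhlhe40 (-0.92), H2-T23 (-0.91), Dusp5 (-0.84) and Per3 (-0.75). The next were Ppargc1a (-0.74), Kbtbd11 (-0.73), Pkm (-0.73), Oasl2 (-0.71), Loxl2 (-0.67), Selenop (-0.55), Npr3 (-0.49), mt-Co1 (-0.48), mt-Co2 (-0.47), Cycs (-0.43), Rps24 (-0.41) and Cyc1 (-0.39). The last were Pdha1 (-0.38), Dusp1 (-0.36) and Cavin2 (-0.35). Positive differences were those of Aqp5 (3.501), Siglecg (3.12), Cd300lb (3.02), Spp1 (2.80), Samd5 (2.79), Hpgds (2.32), Cdh6 (2.20), Itgb6 (2.01), Hsd11b2 (1.92), Vcam1 (1.76), Ccnd1 (1.75) and Nrep (1.72). Then came Cftr (1.63), Sox8 (1.55), Ccdc80 (1.52), Phlda1 (1.503), Kif20a (1.498), Cyp51 (1.48), Col6a2 (1.39), Cxcl12 (1.36), Sprr1a (1.36), Ptprz1 (1.33), Dusp4 (1.32) and Rsad2 (1.31). Also positive were Idi1 (1.30), Tnfrsf9 (1.23), Pcdh18 (1.22), Cxcl10 (1.19), Krt8 (1.15), Tyms (1.10), Prkg2 (1.04), Nr3c1 (0.95), Fst (0.88), Insig1 (0.84), Sprr2g (0.82) and Tk1 (0.78). Further ones were Olfml3 (0.78), Steap4 (0.77), Sqle (0.75), Fosl1 (0.72), Rrm2 (0.71), Bysl (0.70), Stard4 (0.68), Ccl2 (0.68), Inhba (0.63), Col6a1 (0.62), Wfdc1 (0.55) and Ncl (0.55). The last were Rrp12 (0.49) and Gbp2 (0.49).

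The entry without a gene symbol, which no comparison used, lay above its level before treatment (8.20 log2 CPM) in each later group, at 9.08, 8.73 and 8.56 in vehicle and 9.42, 8.95 and 8.54 in corticosterone libraries of days 3, 6 and 9.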

How the results depend on the processing

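Removing the length trend and leaving out single libraries that stood apart were chosen after seeing the data. Counts of genes, lists and shared calls stayed within 1.5 times of those reported under all alternatives run except those with values below, and using no filter changed nothing because no gene fails it. With at least 2-fold change required, which by construction keeps fewer genes, counts were 906, 990 and 296 for corticosterone at days 3, 6 and 9. They were 2076, 1999 and 2048 for vehicle, and 149 and 920 for the changes of effect. At adjusted p under 0.01, again stricter by construction, 2401 genes remained at day 9, 591 for the change from day 3 to day 6 and 990 shared calls at day 9. With the compared groups fitted alone the change from day 3 to day 6 gave 766 genes, and the cause was not tested. Camera with an estimated correlation called 6, 2 and 7 lists at days 3, 6 and 9, 10 for vehicle day 9 and 4 and 7 for the changes of effect. Fry, asking a different question, called 30 and 29 at days 3 and 6.

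In leave-one-out fits counts ranged over 5915 to 6581, 5635 to 5991 and 3128 to 3426 for corticosterone and 8705 to 8796, 8828 to 8925 and 8904 to 8993 for vehicle at days 3, 6 and 9. They ranged over 918 to 1449 and 4644 to 5702 for the changes of effect, and over 4154 to 4910 and 1345 to 1842 for calls shared with day 3. Lists called ranged over 17 to 18, 16 to 18 and 18 to 19 at days 3, 6 and 9 and 20 to 21 for vehicle day 9. Of the values of named genes and counts under all alternatives, 6039 kept direction and call, 45 lost and 8 gained a call, and 15 changed sign. Those 15 were all of Nr3c2, which was never called, and the cause was not tested. At day 6 it was at -0.0185 with quantile normalization, -0.0011 with log2(CPM + 1), -0.0113 with log2(CPM + 5), -0.11 with the replicate block and -6.2e-05 with the random block, and at -0.15 to 0.25 in leave-one-out fits. With library weights it was at 0.0538 at day 3 and -0.10 at day 9, and in leave-one-out fits at -0.20 to 0.0789 and at -0.19 to 0.27. Replicate numbers were not taken to pair the libraries, since deviations of same-numbered libraries correlated at a mean of 0.0747 across genes (-0.290 to 0.371), against -0.0191 for other numbers. Of 10 pairs within a day 5 exceeded 0.1, the 3 of day 6 among them (0.111 to 0.181), so pairing stays open there, and 11 of 28 libraries lay closest to their own number. As a block the number gave 6325, 5993 and 3827 genes for corticosterone, 9145, 9232 and 9280 for vehicle and 1105 and 4953 for the changes of effect, and as a random block its correlation was 0.0173.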

Other observations

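Every test in this part was chosen before its result was seen, except the list of retinoic acid targets, written after the rise of Aldh1a1, and the values without replicate 4. Genes of short lists were named after their values were seen. Brackets give members higher and lower and, after the word alone, those adjusted over the list alone. Genes of fatty acid and triglyceride synthesis fell at day 3 (3 and 13 of 20, alone 3 and 13, median -0.28, camera adjusted p = 0.00378, adjusted p = 0.0845 with an estimated correlation) and at day 9 (1 and 6 of 20, alone 2 and 6, median -0.11, camera adjusted p = 0.0257, adjusted p = 0.173 with an estimated correlation). Genes of the unfolded protein response, to misfolded proteins, were called higher at day 3 (13 and 4 of 28, alone 13 and 4, median 0.09, camera adjusted p = 0.0146, adjusted p = 0.386 with an estimated correlation) and day 6 (15 and 7 of 28, alone 15 and 7, median 0.22, camera adjusted p = 0.0228, adjusted p = 0.443 with an estimated correlation), with 10 higher and 7 lower and a median of 0.03 at day 3 without corticosterone replicate 4. Ribosome biogenesis genes fell at day 3 (2 and 17 of 35, alone 2 and 17, median -0.16, camera adjusted p = 0.0293, adjusted p = 0.380 with an estimated correlation), a call that ended under quantile normalization (camera adjusted p = 0.0637). At day 9 genes of NRF2 and glutathione, the antioxidant defence, rose (11 and 1 of 25, alone 12 and 1, median 0.13, camera adjusted p = 0.000914, adjusted p = 0.221 with an estimated correlation), as did heat shock and chaperone genes (11 and 1 of 19, alone 13 and 2, median 0.19, camera adjusted p = 0.00507, adjusted p = 0.112 with an estimated correlation). Chromatin modifiers fell at day 6 (4 and 13 of 42, alone 4 and 12, median -0.09, camera adjusted p = 0.0228, or 0.323 with an estimated correlation) and at day 9 (1 and 5 of 42, against 1849 and 1887 of all 13128 genes, alone 1 and 5, median -0.13, camera adjusted p = 0.00715, or 0.248 with that estimate). Over the vehicle course to day 9, heat shock genes fell (2 and 14 of 19, alone 2 and 14, median -0.63, camera adjusted p = 0.000174, adjusted p = 0.0413 with an estimated correlation), and so did genes of small RNA biogenesis (5 and 15 of 24, alone 5 and 15, median -0.33, camera adjusted p = 0.0142, adjusted p = 0.0413 with an estimated correlation). Epididymal solute transport genes rose (16 and 3 of 20, alone 16 and 3, median 0.60, camera adjusted p = 0.0329, adjusted p = 0.198 with an estimated correlation), and so did fatty acid and triglyceride synthesis genes (11 and 3 of 20, alone 11 and 3, median 0.30, camera adjusted p = 0.0329, adjusted p = 0.176 with an estimated correlation). Inflammatory genes (15 and 2 of 20, alone 15 and 2, median 0.80, camera adjusted p = 0.00115, adjusted p = 0.0633 with an estimated correlation), receptor targets (20 and 1 of 29, alone 20 and 1, median 0.53, camera adjusted p = 0.00141, adjusted p = 0.3001 with an estimated correlation) and metal binding genes (8 and 2 of 11, alone 8 and 2, median 0.83, camera adjusted p = 0.00617, adjusted p = 0.0803 with an estimated correlation) rose over that course too. Tricarboxylic acid cycle genes fell over it (3 and 13 of 22, alone 3 and 13, median -0.26, camera adjusted p = 0.0291, adjusted p = 0.3001 with an estimated correlation), a call that ended under quantile normalization (camera adjusted p = 0.316). With corticosterone at day 9 ribosomal protein genes rose (8 and 0 of 64, a share below that of all genes, alone 6 and 0, median 0.14, camera adjusted p = 0.000421, or 0.739 with an estimated correlation). Matrix genes fell (6 and 13 of 32, alone 7 and 13, median -0.08, camera adjusted p = 0.0186, or 0.296 with that estimate), and mitochondrially encoded genes rose (4 and 0 of 11, alone 4 and 0, median 0.16, camera adjusted p = 0.00302, or 0.296 with that estimate) except under quantile normalization (camera adjusted p = 0.288).

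The remaining lists were not called with corticosterone on any day, and members higher and lower at day 3 are given with, in brackets, those adjusted over the list alone and the day 3 medians with and without corticosterone replicate 4. They were 3 and 9 of 21 (3 and 9, medians -0.05 and 0.01) for receptor and steroid handling, 8 and 12 of 25 (8 and 12, medians 0.01 and -0.04) for p53 targets and 4 and 6 of 19 (4 and 6, medians -0.06 and -0.15) for epithelial junctions and keratins. Mesenchymal transition had 2 and 10 of 20 (2 and 10, medians -0.13 and -0.21), extracellular vesicles 8 and 12 of 42 (8 and 12, medians -0.05 and -0.08) and small RNA biogenesis 2 and 7 of 24 (2 and 7, medians -0.10 and -0.07). Solute transport had 7 and 7 of 20 (7 and 7, medians -0.12 and -0.08), WNT, TGF-beta and YAP targets 5 and 10 of 21 (6 and 11, medians -0.29 and -0.21) and lysosome and autophagy 11 and 10 of 36 (11 and 10, medians -0.02 and -0.05). Among cell markers, principal cells had 1 and 5 of 10 (1 and 5, medians -0.30 and -0.29), basal cells 3 and 2 of 6 (3 and 2, medians 0.31 and 0.20) and fibroblasts and smooth muscle 3 and 3 of 8 (3 and 3, medians -0.03 and 0.05). Median, mean and test differed in sign at day 3 for p53 targets, lysosome, solute transport and fibroblast lists. Mesenchymal genes were called lower at day 3 under quantile normalization (camera adjusted p = 0.0267). Without this replicate 4 the lower members of NRF2 and glutathione at day 3 went from 6 to 11 and the higher members of receptor and steroid handling from 3 to 6.

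Short lists had too few measured members for a test, and values of members at day 3 passed adjusted p under 0.05 unless marked. Of 21 macrophage and leukocyte markers 3 were measured. At day 3 they were lower with corticosterone, Cd68 (lysosomal, -1.65), Csf1r (-1.71) and Cd14 (-0.56). Over the vehicle course to day 9 they stood at 3.73, -2.35 and 0.75. Of 14 clear or narrow cell markers 4 were measured, Lgals4 (1.52), Atp6v0a4 (-0.78), Atp6v1b2 (-0.40) and Car2 (0.64, not called). Of 20 germ cell genes 3 were measured, Ddx4 (0.98), Gapdhs (0.70) and Odf2 (-0.13, not called). Of 39 histone genes 4 were measured, H1f0 (-0.25), H1f2 (0.25, not called), H2bc4 (0.72) and H2ac18 (0.23, not called).

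Since Aldh1a1 makes retinoic acid, a rise of its targets was tested as a hypothesis. Of 16 targets 9 were measured, 3 higher and 4 lower at day 3, with a median of -0.20 (95% bootstrap interval -1.26 to 0.62). The test did not decide the hypothesis.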
